A study of Mus musculus with 9 samples.

How the data were processed

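RNA was measured in 9 libraries from area CA1 of the mouse hippocampus, and per the labels these form 3 groups of 3 biological replicates: scrambled short hairpin RNA (shRNA) control, H2A.Z shRNA naive, and H2A.Z shRNA trained in contextual fear conditioning. Per the labels, total RNA was taken with RNeasy, polyadenylated RNA was made into directional NEBNext libraries from 1 µg of RNA, and the libraries were sequenced on a HiSeq2000 as 50 bp paired-end reads.

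Per the submitters' processing notes, the authors checked the reads with FastQC, aligned them with TopHat 1.4.0 to the mouse genome mm10 and made values with Cufflinks and Cuffdiff. The authors deposited a table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with a value per gene and library and no counts. The exact step that wrote the table and its gene annotation are not given in the sources used here. The values showed no log scale, and the highest number of identical values, zeros included, shared by any pair of libraries among the genes tested was 66. The table had 24489 rows. Left out were 27 rows whose names had turned into dates, since their gene could no longer be read, and 5651 rows that were 0 in every library. A further 776 rows shared 274 names. Of these, 99 passed the filter and were tested, but none was named or used in a list. Of the symbols tested, 95.4% matched the GENCODE M21 annotation of GRCm38, the same assembly as mm10, and coordinates come from there.

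The depth of each library was not given by counts. Cufflinks values move in steps set by single fragments, so the steps between low FPKM values of the same genes were compared with control replicate 2. Relative depth lay between 0.871 and 1.26. From the level at which single fragments appear in genes with 1 transcript, a gene at 1 FPKM rests on roughly 18.6 to 26.3 fragments per kilobase of transcript. This is an estimate, so no counting interval was computed.

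FPKM values were transformed to log2(FPKM + 1), that is with a pseudocount of 1, and 12327 genes with a mean of at least 1 FPKM over all 9 libraries were tested. The added 1 draws fold changes of genes of low level toward 0, so a log2 fold change of such a gene is smaller than the log2 ratio of its mean FPKM values. No further scaling was applied. A linear model with 3 groups was fitted with limma 3.58.1 in R 4.3.3, with a trend in the prior variance, 6 residual and 2.72 prior degrees of freedom, and two-sided tests. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over all genes tested within a comparison, with a threshold of 0.05. The comparisons were naive against control, trained against control, trained against naive, and the mean of both H2A.Z shRNA groups against control. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for depth and figures. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1; with 6 against 3 there are 84 assignments.

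The comparisons, the tests, the 36 gene lists of pathways and cell type markers, and the rule for named genes were fixed before the data were examined. In each comparison the rule names H2afz and H2afv; in each direction up to 8 genes past the threshold with the largest fold change and groups that do not overlap, or, where no gene passes, the 5 with the smallest unadjusted p; of each list described, up to 4 members with the smallest unadjusted p; and Arc, Fos, Egr1, Npas4, Nr4a1 and Bdnf. Predicted and clone-based genes and small RNA genes are not named by this rule, and genes named outside it are said to be chosen after their values were seen. Lists with at least 5 members tested, 32 in all, were compared with all other genes by camera with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Member counts past the threshold are given over all genes and adjusted over the list alone. The list median is the median log2 fold change of its members.

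Each result was computed again with median-of-ratios scaling, quantile normalization, a pseudocount of 0.1, no filter, a filter of 5 FPKM, array quality weights, a robust prior variance, a fit of only the groups compared, and without each library in turn. Lists were tested again with an estimated correlation and with the self-contained test fry. A further 5 alternatives were added after seeing the data: small RNA genes left out, genes listed at 0 in any library left out, control replicate 1 and naive replicate 2 both left out, the mean of the dentate gyrus markers per library as a covariate, and an exact permutation of the list mean per library. The method was tested on simulated data with the mean and spread of each gene in these libraries and independent noise, for naive against control: 200 changed genes in each of 10 runs were recovered in 87.6%, 94.2% and 99.2% of cases at 1.5-, 2- and 4-fold, with 4.54% of calls false. The changed genes were drawn only from those with a mean log2(FPKM + 1) of at least 2, and the folds were set on that scale. Recovery of genes of lower level, or in comparisons with fewer changed genes, was not tested. The Benjamini-Hochberg adjustment is stricter where fewer genes change, so recovery in the real comparisons can be lower. A shift of 0.5 on the log2 scale in 1 list was found in 20 of 20 runs, with 2 false calls over 29 other lists in those runs. Because genes varied independently there, these runs cannot show how often a list is falsely called when its genes vary together. The overlap of the 2 comparisons that share the controls was set against 50 simulated runs. In each run all 9 libraries were drawn anew with independent noise and no group differences, and both comparisons shared the simulated controls.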

Results

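Polyadenylated RNA from area CA1 of the hippocampus, a field of pyramidal neurons that takes part in contextual memory, was sequenced from C57BL/J6 mice aged 9 to 12 weeks. The 9 libraries form 3 groups of 3 biological replicates. Mice had received an adeno-associated virus, a vector that carries a gene into cells, which encoded a scrambled shRNA in the control group and an shRNA against H2A.Z in the other two groups. H2A.Z is a variant of histone H2A found in nucleosomes at promoters and enhancers. One H2A.Z shRNA group was naive and the other was trained in contextual fear conditioning, in which a mouse learns to associate a chamber with a foot shock. Whether the control mice were trained, and how long after training the tissue was taken, is not given in the sources used here. All levels are FPKM as mean ± SD of 3 libraries, unless another number is given.

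By the steps between low values, a gene at 1 FPKM rested on about 18.6 to 26.3 fragments per kilobase of transcript. Total FPKM ranged from 296327 to 442251, and from 270448 to 286467 once small RNA genes were left out. Across 12327 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.959 to 0.976 within groups and 0.945 to 0.975 between groups. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes of low level.

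The level of the targeted mRNA differed between groups by less than the spread between libraries. H2afz, which encodes H2A.Z.1, lies on chromosome 3, 137864487 to 137866922, plus strand, GRCm38. It stood at 27.1 ± 1.43 in the control libraries, 27.0 ± 1.63 in the libraries labelled H2A.Z shRNA naive and 26.0 ± 2.31 in those labelled H2A.Z shRNA trained. The log2 fold change of both H2A.Z shRNA groups against control was -0.03 (SE 0.06, limma adjusted p = 0.844). Its 95% confidence interval corresponded to 0.886 to 1.08 times the control level of FPKM + 1. H2afv on chromosome 11, which encodes the second form, H2A.Z.2, stood at 15.03 ± 0.993, 15.6 ± 0.217 and 14.2 ± 1.04. Its log2 fold change was -0.01 (SE 0.05, limma adjusted p = 0.939). Neither gene passed the threshold in any of the 4 comparisons, although H2afv was lower in each trained than in each naive library (log2 fold change -0.14, SE 0.06, limma adjusted p = 0.606). The 26 measured genes of the complexes that exchange H2A.Z, such as Actl6b, Yeats4, Actl6a and Nfrkb, had a median log2 fold change of 0.03 in both groups against control (camera adjusted p = 0.301). A drop of the target is therefore not seen in these values, and every direction given here is between groups as the libraries are labelled.

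**Figure D1:**
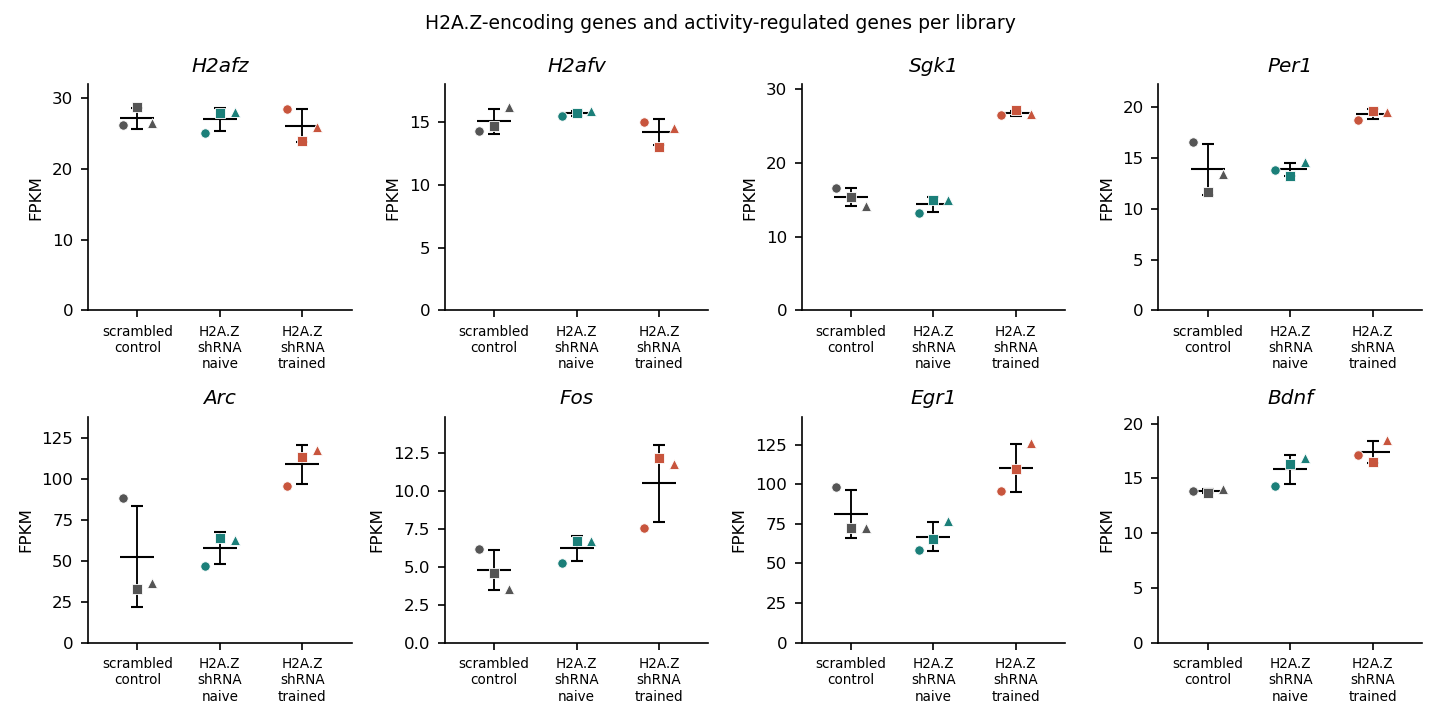
FPKM (vertical axes, from 0) of the H2A.Z genes H2afz and H2afv and of 6 activity-regulated genes in the 3 groups; points are libraries (circle, square and triangle for replicates 1, 2 and 3), long bars group means and error bars SD. H2afz lies near 27.1, 27.0 and 26.0 in the 3 groups, Sgk1 near 26.7 in all trained libraries against 14.4 in the naive ones, and Arc in control replicate 1 at 88.4 against 32.9 and 36.8 in the other control libraries.

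The comparison of the libraries labelled H2A.Z shRNA naive with the scrambled controls sets the H2A.Z hairpin without training against the scrambled one, and it also holds a difference in training if the control mice were trained. Genes of antigen presentation, interferon-stimulated genes, markers of dentate gyrus granule neurons and markers of microglia were higher as groups in the naive libraries. Markers of CA1 pyramidal neurons and ion channel genes were lower, and none of these 6 calls was kept with an estimated correlation (adjusted p = 0.252 with an estimated correlation for ion channel genes and 0.587 for the other lists). No single gene passed the threshold in limma after adjustment (0 higher and 0 lower, smallest adjusted p = 0.0696). An unadjusted p under 0.05 was seen for 1911 genes, 1209 of them higher, against 616 by chance. The ranges of the groups did not overlap for 2393 genes, or 19.4%, where chance gives 10%.

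All 16 measured antigen presentation genes had estimates above 0, with a median log2 fold change of 1.70 (camera adjusted p = 9.80e-09; adjusted p = 0.587 with an estimated correlation). Over all genes 0 of them passed, and 15 passed adjusted over the list alone. H2-T23, a class Ib histocompatibility gene, stood at 7.33 ± 2.53 in control and 37.6 ± 32.6 in naive libraries. Psmb8, a subunit of the immunoproteasome, stood at 3.21 ± 0.770 and 16.5 ± 14.0, and Tap1, a peptide transporter, at 1.42 ± 0.663 and 7.67 ± 5.97. H2-Q7, one of a family of near-identical genes whose reads are hard to assign, stood at 0.268 ± 0.235 and 4.09 ± 3.77. Interferon-stimulated genes had a median of 0.92, with 28 of 29 above 0 (camera adjusted p = 6.00e-08; adjusted p = 0.587 with an estimated correlation). Of its members 0 passed over all genes, and 0 adjusted over the list alone. Among them the chemokine Cxcl10 stood at 2.07 ± 1.16 and 19.4 ± 13.5. Gbp2, a guanylate-binding protein gene named here after its values were seen, stood at 2.28 ± 0.735 and 25.8 ± 26.9. Without naive replicate 2 the antigen presentation median was 1.048, and the interferon median was 1.54 without naive replicate 1 and 0.60 without naive replicate 3. With the dentate granule markers of each library as a covariate these medians were 2.58 and 1.60.

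Microglial markers had a median of 0.45, with 21 of 22 above 0 (camera adjusted p = 9.49e-07; adjusted p = 0.587 with an estimated correlation). They included Itgam at 4.66 ± 0.682 and 7.26 ± 1.81, Fcer1g at 9.93 ± 1.08 and 19.1 ± 7.40, and Aif1 at 6.08 ± 0.411 and 12.3 ± 6.14. Reactive astrocyte genes had a median of 0.36 (camera adjusted p = 0.00298; adjusted p = 0.587 with an estimated correlation). This list shares Cxcl10 with the interferon list and includes the filament gene Vim at 16.4 ± 2.75 and 25.8 ± 9.13, and its call ended without naive replicate 2 (median 0.18), also with control replicate 1 left out besides (0.14). The microglial median was 0.23 without naive replicate 2. With the dentate covariate the microglial median was 0.68 and that of the reactive astrocyte genes 0.63. The naive libraries differed from each other in immune genes. Cd74, the invariant chain of class II molecules, stood at 22.6, 125 and 3.30 in them against 0.401, 2.33 and 1.21 in the controls.

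Markers of dentate gyrus granule neurons were above 0 in 19 of 19 genes, with a median of 0.57 (camera adjusted p = 1.26e-08; adjusted p = 0.587 with an estimated correlation). Over all genes 0 passed, and 8 passed adjusted over the list alone. Prox1, the transcription factor of granule neurons, stood at 13.5 ± 4.83 and 24.4 ± 4.59. Capn3, a calpain protease, stood at 2.50 ± 0.613 and 5.05 ± 0.424, and Tdo2, an enzyme of tryptophan breakdown, at 3.06 ± 1.22 and 5.97 ± 0.725. The control libraries themselves differed in these markers, with list means of 3.84, 3.20 and 3.07 on the log2 scale, against 4.08, 3.84 and 3.99 in the naive libraries. Markers of CA1 pyramidal neurons had a median of -0.29, with 10 of 11 below 0 (camera adjusted p = 0.000460; adjusted p = 0.587 with an estimated correlation). Gpr161, at 16.4 ± 0.422 and 10.7 ± 1.71, was the 1 member past the threshold adjusted over the list alone, beside 0 over all genes. The dentate median was 0.87 without control replicate 1, and the CA1 median -0.18 without control replicate 3. The CA1 call ended with the dentate covariate (median 0.03).

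Ion channel genes had a median of -0.11, with 26 of 35 below 0 (camera adjusted p = 0.000139; adjusted p = 0.252 with an estimated correlation). Of its members 0 passed over all genes, and 5 adjusted over the list alone. The calcium channel gene Cacna1a stood at 15.6 ± 0.503 and 13.2 ± 0.297 and the pacemaker channel gene Hcn2 at 34.5 ± 4.43 and 25.1 ± 0.817. Ribosomal protein genes had a median of 0.10, with 72 of 78 above 0 (camera adjusted p = 9.16e-06; adjusted p = 0.587 with an estimated correlation). Nuclear genes of the respiratory chain had a median of -0.07, with 41 of 46 below 0 (camera adjusted p = 5.23e-05; adjusted p = 0.602 with an estimated correlation). Oligodendrocyte markers had a median of -0.29 (camera adjusted p = 0.000219; adjusted p = 0.587 with an estimated correlation), with Mbp, a myelin protein, at 677 ± 197 and 473 ± 137. Choroid plexus and ependymal markers had a median of -0.43 (camera adjusted p = 0.000363; adjusted p = 0.587 with an estimated correlation). This call ended without control replicate 3 (median -0.07), in which Ttr, the transthyretin gene of the choroid plexus, stood at 763.9 against 33.2 and 132.1 in the other controls. Heat shock and unfolded protein genes had a median of -0.13, presynaptic genes -0.10 and cell cycle genes 0.11 (camera adjusted p = 0.000474, 0.00273 and 0.0420; adjusted p = 0.590, 0.587 and 0.587 with an estimated correlation). The heat shock call ended without control replicate 1 (median 0.01) or naive replicate 1 (-0.04), and the oligodendrocyte call without control replicate 2 (-0.11). The cell cycle call ended without control replicate 1 (0.11), naive replicate 2 (0.09), naive replicate 3 (0.05) or trained replicate 2 (0.11). It ended also with a filter of 5 FPKM (0.06), quantile normalization (0.05) and array weights (0.09), and the heat shock call with array weights (-0.06). The respiratory chain median was -0.13, -0.04 and -0.04 without control replicates 1, 2 and 3, and -0.03 without naive replicate 1. The oligodendrocyte median was -0.16 without naive replicate 1 and -0.46 without naive replicate 3, and the ribosomal one 0.06 without naive replicate 3. Presynaptic and heat shock medians were -0.06 and -0.23 without control replicate 2, that of the choroid plexus -0.66 without control replicate 1 and that of the cell cycle 0.22 without control replicate 3. The dentate covariate ended the calls of the respiratory chain (0.07), oligodendrocyte (0.03), choroid plexus (-0.10) and presynaptic genes (-0.03). It gave medians of 0.19 for ribosomal protein, -0.34 for heat shock and 0.21 for cell cycle genes. With a pseudocount of 0.1 the cell cycle median was 0.17 and that of the choroid plexus -0.67. Leaving out control replicate 1 and naive replicate 2 together ended the calls of presynaptic (-0.11), ribosomal protein (0.04), heat shock (-0.05) and cell cycle genes (0.07).

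The single gene with the smallest p was Ralyl, which encodes an RNA-binding protein, at 23.8 ± 1.22 in control and 31.6 ± 0.353 in naive libraries (log2 fold change 0.40, SE 0.04, limma adjusted p = 0.0696). Next among the higher ones were the cell adhesion gene Alcam at 18.7 and 26.3, Marcks, a substrate of protein kinase C, at 39.5 and 48.2, Trafd1 at 14.7 and 20.2, and Capn3. With lower values, Lingo3 stood at 21.2 and 16.3, the sodium-calcium exchanger gene Slc24a2 at 89.4 and 69.1, and Zmat3, a target of p53, at 19.9 and 15.2. Gpr161 and Shb, at 4.36 and 3.08, were the others. For these other 9 genes the limma adjusted p lay between 0.146 and 0.188. Without control replicate 1, 10 genes were higher and 5 lower past the threshold, and without naive replicate 1, 13 were higher. Without control replicate 3, 3 were higher, 2 of them listed at 0 in some library. Without naive replicate 3, 4 rows were higher and 1 lower. Of the 4, 1 gene is listed at 0 in some library and the others are small RNA rows, 2 of them with the same name and values. The 1 lower row is listed at 0 in some library and shares its name with another row.

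The comparison of the libraries labelled H2A.Z shRNA trained with the scrambled controls holds the hairpin and, if the control mice were not trained, the training as well. Sgk1, which encodes a kinase induced by glucocorticoids and by neuronal activity, lies on chromosome 10, 21882184 to 21999903, plus strand. It rose from 15.4 ± 1.20 to 26.7 ± 0.346 (log2 fold change 0.76, SE 0.07, limma adjusted p = 0.0177), with 3 of 3 trained libraries above every control library. It was the 1 gene higher past the threshold, with 0 lower, and 951 had an unadjusted p under 0.05 against 616 by chance. Immediate early genes, antigen presentation genes, and markers of microglia and of dentate granule neurons were higher as groups in the trained libraries, and genes of the respiratory chain were lower. None of these 5 calls was kept (adjusted p = 0.525 with an estimated correlation for immediate early genes and 0.737 for the other lists). The ranges of the groups did not overlap for 1539 genes, or 12.5%, where chance gives 10%. The call of Sgk1 ended without control replicate 2 (limma adjusted p = 0.161), naive replicate 2 (0.0531) or trained replicate 1 (0.0766), 2 (0.0883) or 3 (0.184). It also ended with no filter (limma adjusted p = 0.0502) and with the dentate markers as a covariate (0.106), in a range of 0.00508 to 0.184 over all alternatives. Without control replicate 1, 18 genes were higher and 7 lower. Without control replicate 3 or naive replicate 3, 2 were higher, Sgk1 and 1 gene listed at 0 in some library.

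Immediate early genes, which neurons transcribe within minutes of activity, had a median of 0.32, with 34 of 37 above 0 (camera adjusted p = 2.26e-15; adjusted p = 0.525 with an estimated correlation). Over all genes 0 of them passed, and 15 passed adjusted over the list alone. Fos, a subunit of the AP-1 transcription factor, stood at 4.76 ± 1.31 in control and 10.5 ± 2.55 in trained libraries. Bdnf, a neurotrophin, stood at 13.9 ± 0.184 and 17.4 ± 1.01, Per1, a clock gene, at 13.9 ± 2.47 and 19.3 ± 0.488, and Dusp1, a phosphatase of MAP kinases, at 5.55 ± 0.591 and 7.59 ± 0.962. Arc, which encodes a protein of activated synapses, stood at 52.7 ± 31.0 and 108.9 ± 11.7 (log2 fold change 1.17, limma adjusted p = 0.557). It passed without control replicate 1, in which it stood at 88.4 (log2 fold change 1.61, limma adjusted p = 0.0161; range over alternatives 0.0161 to 0.974). Egr1 stood at 81.3 and 110.5, Nr4a1 at 34.6 and 51.2, and Npas4 at 1.85 and 2.18. Clock and glucocorticoid-induced genes had a median of 0.08, with 21 of 28 above 0 (camera adjusted p = 0.000116; adjusted p = 0.525 with an estimated correlation). Of them 1 passed over all genes, Sgk1, and 4 adjusted over the list alone, the others being Per1, Nfkbia at 10.01 and 13.7, and Errfi1 at 13.2 and 16.3. Dentate granule markers moved the same way, with a median of 0.34 and 19 of 19 above 0 (camera adjusted p = 2.41e-05; adjusted p = 0.737 with an estimated correlation). Their list means were 3.99, 3.43 and 3.60 in the trained libraries. The dentate median was 0.59 without control replicate 1, 0.14 without control replicate 3 and 0.17 without trained replicate 1.

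Antigen presentation genes had a median of 1.26, with 14 of 16 above 0 (camera adjusted p = 3.48e-08; adjusted p = 0.737 with an estimated correlation). Of its members 0 passed over all genes, and 8 adjusted over the list alone. Cd74 stood at 1.32 ± 0.971 and 48.2 ± 20.01, H2-Aa, a chain of a class II molecule, at 0.477 ± 0.178 and 14.8 ± 5.67, and H2-D1, a class I molecule, at 22.7 ± 5.75 and 80.9 ± 30.5. Microglial markers had a median of 0.36, with 21 of 22 above 0 (camera adjusted p = 7.60e-08; adjusted p = 0.737 with an estimated correlation). The receptor gene Trem2 stood at 7.67 ± 0.619 and 11.7 ± 2.93 and the cathepsin gene Ctss at 53.2 ± 9.52 and 107.2 ± 29.2. The microglial median was 0.23 without trained replicate 2. Interferon-stimulated genes had a median of -0.29 and did not pass (camera adjusted p = 0.0583).

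Respiratory chain genes were below 0 in 46 of 46, with a median of -0.11 (camera adjusted p = 1.45e-08; adjusted p = 0.737 with an estimated correlation), for example Uqcrfs1 at 74.1 ± 4.22 and 64.4 ± 4.05. Markers of oligodendrocyte precursors had a median of -0.11, with 12 of 14 below 0 (camera adjusted p = 0.0180; adjusted p = 0.737 with an estimated correlation). Pdgfra stood at 7.44 ± 0.604 and 6.18 ± 0.641 and Olig2 at 10.4 ± 1.08 and 8.22 ± 0.921. Presynaptic genes had a median of -0.10, choroid plexus markers -0.36 and chromatin modifiers 0.03 (camera adjusted p = 0.00313, 0.0257 and 0.0334; adjusted p = 0.737 with an estimated correlation for each). The chromatin list included Ezh2, a histone H3 methyltransferase, at 1.4005 ± 0.196 and 2.001 ± 0.166. The presynaptic call ended without control replicate 2 (median -0.05), and the precursor call without control replicate 1 (-0.18) or trained replicate 1 (-0.03). The choroid plexus call ended without control replicate 3 (-0.01) or trained replicate 2 (-0.40), and the chromatin call without control replicate 2 (0.01), control replicate 3 (0.03) or trained replicate 1 (0.01). The respiratory chain median was -0.16 without control replicate 1, -0.07 without control replicate 3 and -0.04 with the dentate covariate. The presynaptic median was -0.06 without trained replicate 1 or with quantile normalization and -0.05 with that covariate, and the precursor median -0.17 without trained replicate 2. Without control replicate 1 the choroid plexus median was -0.61 and the chromatin median 0.05, and the latter was 0.05 without trained replicate 3. The dentate covariate ended the precursor (-0.05), choroid plexus (-0.17) and chromatin calls (9.9e-05), and a filter of 5 FPKM the choroid plexus (-0.37) and chromatin calls (0.02).

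The comparison of the trained with the naive libraries asks what training changed among mice labelled H2A.Z shRNA, and also tests whether the differences of these groups from control are unequal. Sgk1 rose from 14.4 ± 1.02 in naive to 26.7 ± 0.346 in trained libraries (log2 fold change 0.85, SE 0.07, limma adjusted p = 0.00689), in 3 of 3 libraries. Immediate early genes and clock and glucocorticoid-induced genes were higher as groups in the trained libraries, calls that were not kept with an estimated correlation (adjusted p = 0.293 with an estimated correlation for each). Interferon-stimulated genes, dentate granule markers and astrocyte markers were lower, which was not kept either (adjusted p = 0.483, 0.703 and 0.618 with an estimated correlation). The dentate call ended also without trained replicate 2 (median -0.19) and the astrocyte call without naive replicate 2 (-0.07). Besides Sgk1, no gene passed in limma (1 higher, 0 lower), and 1020 had an unadjusted p under 0.05, 682 of them lower, against 616 by chance. Ranges did not overlap for 1843 genes, or 14.95%, where chance gives 10%. The call of Sgk1 ended in 1 alternative, without trained replicate 3 (limma adjusted p = 0.0811, range over alternatives 0.00161 to 0.0811). Without naive replicate 1, 24 genes were lower past the threshold, among them Isg15 and Cxcl10.

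Immediate early genes had a median of 0.27, with 33 of 37 above 0 (camera adjusted p = 4.59e-16; adjusted p = 0.293 with an estimated correlation). Over all genes 0 of them passed, and 5 adjusted over the list alone. Egr1, a zinc finger transcription factor, stood at 66.8 ± 9.05 in naive and 110.5 ± 15.2 in trained libraries, and Egr4 at 11.6 ± 1.30 and 16.7 ± 2.17. The nuclear receptor gene Nr4a3 stood at 11.2 ± 0.495 and 14.7 ± 0.998, and the phosphatase gene Dusp5 at 6.21 ± 1.12 and 10.05 ± 1.49. Arc stood at 57.8 ± 9.55 and 108.9 ± 11.7, Fos at 6.21 ± 0.839 and 10.5 ± 2.55, and Bdnf at 15.8 ± 1.31 and 17.4 ± 1.01. Nr4a1 stood at 35.5 and 51.2 and Npas4 at 1.64 and 2.18. Clock and glucocorticoid-induced genes had a median of 0.09, with 21 of 28 above 0 (camera adjusted p = 1.24e-07; adjusted p = 0.293 with an estimated correlation). Over all genes 1 of them passed, Sgk1, and 6 adjusted over the list alone. Tsc22d3, a glucocorticoid-induced gene, stood at 29.6 ± 2.71 and 38.9 ± 1.20, Per1 at 13.9 ± 0.669 and 19.3 ± 0.488, and Ciart, a clock gene, at 3.69 ± 0.682 and 5.11 ± 0.122.

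Late activity genes had a median of 0.08 and ion channel genes of 0.02 (camera adjusted p = 0.00934 and 0.00628; adjusted p = 0.644 and 0.293 with an estimated correlation). These calls ended without naive replicate 1 (median 0.04) and without naive replicate 3 (0.03), respectively. The markers of CA1 neurons had a median of 0.17, with 9 of 11 above 0 (camera adjusted p = 0.00406; adjusted p = 0.582 with an estimated correlation). Of its members 0 passed over all genes, and 3 adjusted over the list alone, and Gpr161 stood at 10.7 ± 1.71 and 15.4 ± 1.48. Dentate granule markers had a median of -0.28, with 18 of 19 below 0 (camera adjusted p = 0.00104; adjusted p = 0.703 with an estimated correlation), a call that ended without trained replicate 2 (median -0.19). The dentate median was -0.44 without trained replicate 1. The CA1 median was 0.11 without naive replicate 1, 0.27 without naive replicate 2 and 0.10 without trained replicate 3. The dentate covariate ended the calls of the CA1 markers (median 0.01) and of the late activity genes (-0.02). The late activity median was 0.14 and 0.05 without trained replicates 1 and 2, 0.04 with no filter and 0.12 with quantile normalization. For ion channel genes it was 0.05, 0.05 and 0.04 without naive replicate 1, trained replicate 1 and trained replicate 3, and 0.04 with the covariate. Median-of-ratios scaling, quantile normalization and a filter of 5 FPKM gave 0.04, 0.04 and 0.03. Their call ended also without control replicate 1 and naive replicate 2 together (0.01).

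Interferon-stimulated genes had a median of -1.28, with 28 of 29 below 0 (camera adjusted p = 1.59e-16; adjusted p = 0.483 with an estimated correlation). Over all genes 0 of them passed, and 17 adjusted over the list alone. Isg15, a ubiquitin-like protein, stood at 29.5 ± 21.7 in naive and 2.61 ± 0.779 in trained libraries. Cxcl10 stood at 19.4 ± 13.5 and 1.53 ± 1.00, and Oasl2, an antiviral gene, at 20.7 ± 14.0 and 2.53 ± 0.894. Histone genes, many of which are near-identical copies whose reads cannot be fully assigned, were below 0 in 16 of 16. Their median was -0.13 (camera adjusted p = 0.00104; adjusted p = 0.483 with an estimated correlation). Without naive replicate 3 it was -0.08.

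Astrocyte markers had a median of -0.12, with 18 of 21 below 0 (camera adjusted p = 0.000733; adjusted p = 0.618 with an estimated correlation). Hes5, a target of Notch signalling, at 3.98 ± 0.190 and 2.66 ± 0.337, was the 1 member past the threshold adjusted over the list alone, beside 0 over all genes. Endothelial markers had a median of -0.12 and meningeal markers of -0.24 (camera adjusted p = 0.0167 and 0.0372; adjusted p = 0.734 and 0.635 with an estimated correlation). The tight junction gene Cldn5 stood at 23.04 ± 2.23 and 16.4 ± 1.401 and the proteoglycan gene Dcn at 5.92 ± 1.12 and 3.31 ± 0.855. Oligodendrocyte markers had a median of 0.17, with 20 of 20 above 0, and ribosomal protein genes a median of -0.08 (camera adjusted p = 0.000508 and 0.000482; adjusted p = 0.703 and 0.734 with an estimated correlation). Heat shock genes had a median of 0.03 and choroid plexus markers of 0.22 (camera adjusted p = 0.0375 and 0.0455; adjusted p = 0.738 and 0.734 with an estimated correlation). The astrocyte call ended without naive replicate 2 (median -0.07), and the endothelial call without naive replicate 2 (-0.06) or trained replicate 1 (-0.09). The meningeal call ended without control replicate 1 (-0.24), naive replicate 2 (-0.18) or trained replicate 3 (-0.13). The oligodendrocyte call ended without naive replicate 1 (0.06) and the ribosomal call without naive replicate 3 (-0.05). The choroid plexus call ended without control replicate 2 (0.22), naive replicate 1 (0.17), naive replicate 2 (0.27), trained replicate 1 (0.20) or trained replicate 3 (0.17). The heat shock call ended without naive replicate 1 (-0.06) or trained replicate 1 (-0.01), with medians of the opposite sign. It ended also with no filter (0.03), median-of-ratios scaling (0.05), quantile normalization (0.06) and array weights (-0.01). The heat shock median was 0.08, 0.07 and 0.08 without naive replicate 2, naive replicate 3 and trained replicate 3. The oligodendrocyte median was 0.11 and 0.36 without naive replicates 2 and 3, and 0.29 and 0.09 without trained replicates 1 and 2. The ribosomal median was -0.14 without naive replicate 1, and that of the choroid plexus 0.12 without control replicate 3 and 0.38 without naive replicate 3. The dentate covariate ended the oligodendrocyte (0.03), choroid plexus (-0.02) and meningeal calls (-0.20), and gave medians of -0.21 for endothelial, -0.13 for ribosomal and 0.10 for heat shock genes. Leaving out control replicate 1 and naive replicate 2 together ended the ribosomal (-0.06), astrocyte (-0.07), endothelial (-0.06) and meningeal calls (-0.18). A filter of 5 FPKM ended the choroid plexus (0.11) and meningeal calls (-0.07). The choroid plexus call ended with median-of-ratios scaling (0.23) and quantile normalization (0.32), and the meningeal one with a fit of only the groups compared (-0.24). The choroid plexus median was 0.41 with a pseudocount of 0.1, the meningeal one -0.10 with no filter and the ribosomal one -0.05 with quantile normalization.

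Setting both H2A.Z shRNA groups, 6 libraries, against the 3 controls gives the mean of their differences, to which the groups can contribute unequally. Antigen presentation genes, microglial markers and dentate granule markers were higher as groups in the libraries labelled H2A.Z shRNA, and respiratory chain and presynaptic genes were lower, each with a call in the same direction in naive and in trained against control, which share the same 3 controls. None of these 5 calls was kept (adjusted p = 0.638 with an estimated correlation for the respiratory chain and 0.613 for the other lists), and the respiratory chain call ended also with the dentate covariate (median 0.01). Immediate early genes were higher on average and ion channel genes lower, without a call in both of these comparisons (adjusted p = 0.613 and 0.447 with an estimated correlation). In limma 0 genes were higher and 0 lower past the threshold (smallest adjusted p = 0.0796). An unadjusted p under 0.05 was seen for 1526 genes, 877 of them higher, against 616 by chance. Without control replicate 1, 25 genes were higher and 12 lower, and without control replicate 3, naive replicate 1, naive replicate 3 and trained replicate 2, 3, 2, 4 and 1 genes were higher. Of these, 2, 2, 1 and 0 are genes other than small RNA genes listed at 0 in some library. The rest without naive replicate 3 or trained replicate 2 are small RNA rows, 2 of them with the same name and values.

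Antigen presentation genes were above 0 in 16 of 16, with a median of 1.42 (camera adjusted p = 7.14e-10; adjusted p = 0.613 with an estimated correlation). Of its members 0 passed over all genes, and 13 adjusted over the list alone. Cd74 stood at 1.32 ± 0.971 in control and 49.3 ± 43.4 in the 6 other libraries, and H2-Ab1, a class II chain, at 0.388 ± 0.0907 and 13.3 ± 14.9. In the exact permutation of the list mean over 84 assignments, p was 0.0238 for antigen presentation, and 0.381 after Benjamini-Hochberg adjustment over the lists. Ion channel genes had the same values. With 84 assignments a single list cannot pass after that adjustment. Microglial markers had a median of 0.42 and dentate markers of 0.46 (camera adjusted p = 2.63e-08 for each; adjusted p = 0.613 with an estimated correlation for each). Csf1r, a receptor of microglia, stood at 18.6 ± 2.06 and 25.3 ± 4.85, and the dentate marker Stxbp6 at 31.5 ± 11.8 and 48.9 ± 10.8. Immediate early genes had a median of 0.18, with 31 of 37 above 0 (camera adjusted p = 2.32e-05; adjusted p = 0.613 with an estimated correlation). Over all genes 0 of them passed, and 2 adjusted over the list alone, Btg2 at 4.38 ± 0.981 and 6.38 ± 0.494 and Bdnf at 13.9 ± 0.184 and 16.6 ± 1.35. The naive libraries alone had an immediate early median of 0.04 against control, with 22 of 37 above 0 (camera adjusted p = 0.771), and the trained ones 0.32, with 34 of 37. Respiratory chain genes were below 0 in 46 of 46, with a median of -0.09 (camera adjusted p = 6.46e-08; adjusted p = 0.638 with an estimated correlation), such as Cox5a at 143 ± 7.28 and 126 ± 6.73. Presynaptic and ion channel genes each had a median of -0.08 (camera adjusted p = 0.000906 for each; adjusted p = 0.613 and 0.447 with an estimated correlation). The synapsin gene Syn1 stood at 109.6 ± 1.43 and 101.4 ± 2.61 and Hcn2 at 34.5 ± 4.43 and 25.8 ± 1.62. Ion channel genes had a median of -0.11 in naive and -0.05 in trained against control (camera adjusted p = 0.000139 and 0.0659). Their call ended without control replicate 1 (-0.10), also with naive replicate 2 left out besides (-0.11). The dentate median was 0.74 without control replicate 1 and 0.27 without control replicate 3, and the respiratory chain median -0.14 and -0.06. Without control replicate 2 the immediate early median was 0.12 and the presynaptic one -0.05, and the immediate early median was 0.12 with a filter of 5 FPKM. The dentate covariate ended the respiratory chain call (0.01) and gave a presynaptic median of -0.05.

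Interferon-stimulated genes had a median of 0.30, reactive astrocyte genes of 0.25 and ribosomal protein genes of 0.06 (camera adjusted p = 0.0190, 0.00773 and 0.000598; adjusted p = 0.749, 0.643 and 0.645 with an estimated correlation). Choroid plexus markers had a median of -0.39, CA1 markers of -0.20 and oligodendrocyte markers of -0.22 (camera adjusted p = 0.000906, 0.00362 and 0.00746; adjusted p = 0.613, 0.613 and 0.672 with an estimated correlation). Heat shock genes had a median of -0.12 and oligodendrocyte precursor markers of -0.09 (camera adjusted p = 0.00248 and 0.0315; adjusted p = 0.645 and 0.613 with an estimated correlation). Of these lists, the choroid plexus markers alone passed in naive and in trained against control. Interferon-stimulated genes lay in opposite directions, with a median of 0.92 in naive and -0.29 in trained against control, where 26 of 29 were below 0, so their mean describes neither group. Medians in naive and trained against control were 0.36 and 0.10 for reactive astrocyte, 0.10 and 0.02 for ribosomal protein, and -0.13 and -0.10 for heat shock genes. For CA1 markers they were -0.29 and -0.08, for oligodendrocyte markers -0.29 and -0.11, and for precursor markers -0.04 and -0.11. Without control replicate 1 the calls of the interferon (median 0.17), reactive astrocyte (0.22), ribosomal protein (0.02), heat shock (0.04) and precursor genes (-0.14) ended. Without control replicate 3 those of the choroid plexus (-0.02), CA1 (-0.07), precursor (-0.08) and interferon lists (0.24) ended. The oligodendrocyte call ended without control replicate 2 (-0.04) or trained replicate 1 (-0.16), the precursor call also without trained replicate 1 (-0.06). The interferon call ended also without naive replicate 2 (0.16), naive replicate 3 (0.17) or trained replicate 3 (0.26). Its median was 0.49 without control replicate 2 and 0.55 without naive replicate 1. The reactive astrocyte median was 0.40 without control replicate 3 and 0.16 without naive replicate 2. Heat shock genes had -0.22 without control replicate 2 and -0.07 without naive replicate 1, and choroid plexus markers -0.60 without control replicate 1. The dentate covariate ended the CA1 (0.00073), oligodendrocyte (0.06), precursor (-0.02) and choroid plexus calls (-0.15). It gave medians of 0.65 for interferon, 0.50 for reactive astrocyte, -0.27 for heat shock and 0.13 for ribosomal protein genes. Leaving out control replicate 1 and naive replicate 2 together ended the interferon (0.06), reactive astrocyte (0.12), heat shock (0.0066), ribosomal (0.0052) and precursor calls (-0.16). Array weights ended the heat shock call (-0.04) and gave a ribosomal median of 0.03. A filter of 5 FPKM ended the precursor call (-0.09) and gave a reactive astrocyte median of 0.40, and quantile normalization an interferon median of 0.19.

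Among single genes with the smallest p were Ralyl at 23.8 and 30.9, Agmo, an enzyme of ether lipid breakdown, at 1.80 and 3.07, and Alcam at 18.7 and 25.2. Cyld, a deubiquitinase, stood at 13.9 and 19.7. Lower values were seen for the channel gene Panx2 at 38.8 and 32.7, Cox6b2 at 3.32 and 1.23, and Pstk at 7.23 and 5.79. The peptide hormone gene Apln stood at 10.04 and 7.14 and Rasgrp2 at 3.86 and 2.71. For these 9 genes the limma adjusted p lay between 0.0796 and 0.233.

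**Figure D2:**
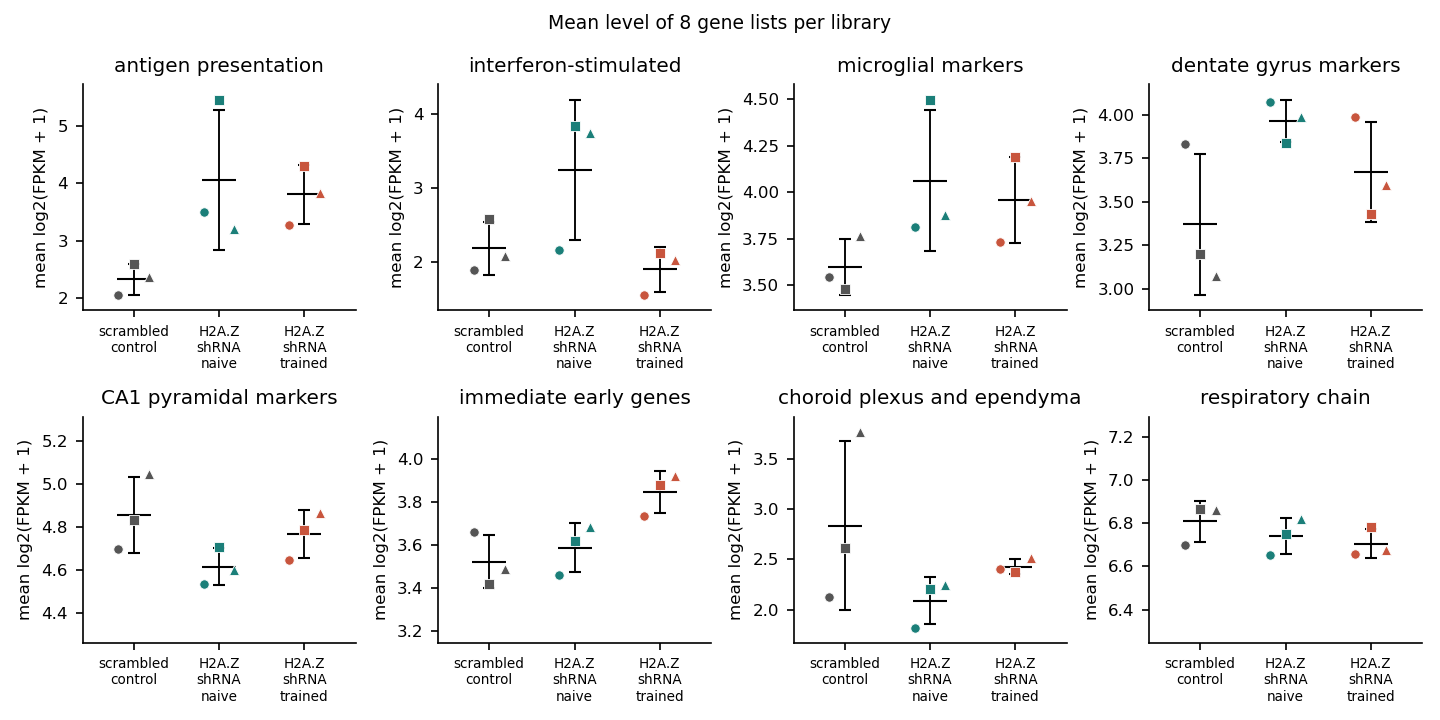
Mean log2(FPKM + 1) of the measured members of 8 gene lists in each library (vertical axes, not starting at 0), by group; points are libraries (circle, square and triangle for replicates 1, 2 and 3), long bars group means and error bars SD. Dentate gyrus markers stand at 3.84 in control replicate 1 against 3.20 and 3.07 in the other controls, and antigen presentation at 5.46 in naive replicate 2.

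**Figure D3:**
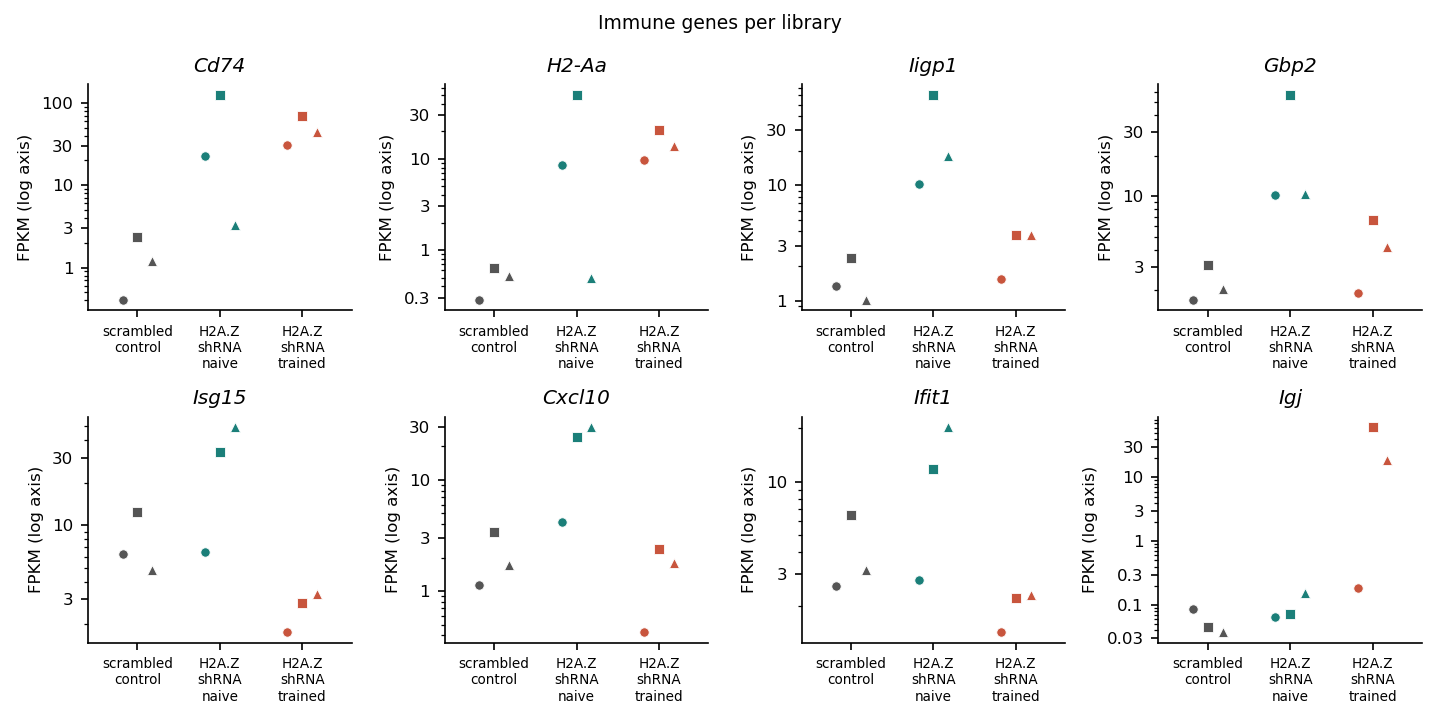
FPKM on a log axis of 8 immune genes, chosen after their values were seen, with each point a library (circle, square and triangle for replicates 1, 2 and 3) and groups along the horizontal axis. Cd74 is at 22.6 and 125 in naive replicates 1 and 2 and at 3.30 in naive replicate 3, and Isg15 is at 49.5 in naive replicate 3 and at most 3.26 in the trained libraries.

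The differences of the naive and the trained groups from the shared controls were compared gene by gene. Across genes, which are not independent replicates, r was 0.634. In 50 simulated runs with unchanged groups and shared simulated controls it was 0.489 on average, with a range of 0.275 to 0.692. The covariance of the log2 fold changes was 0.0534, against 0.0289 on average and 0.0126 to 0.0478, and 72.2% of genes had the same sign, against 66.7%. Without genes listed at 0 in any library, r was 0.618 (simulated 0.432 to 0.552) and the covariance 0.0195 (simulated 0.00609 to 0.00895). Genes varied independently in the simulation, whereas in the real controls sets of genes such as the dentate markers differed together. The simulated range can thus be too narrow, so values outside it do not show an effect shared by both groups. No gene passed the threshold in both comparisons in limma, with 0 past it in naive against control and 1 in trained against control, and 0 were expected from independent lists. The glutamate and GABA synapse genes, the CREB and MAP kinase genes, p53 targets, and markers of CA3, cortex, thalamus and interneurons passed by camera in none of the 4 comparisons. With fry for changes in either direction, p53 targets passed in naive against control, trained against naive and both against control (fry adjusted p = 0.00766, 0.0467 and 0.0213).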

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

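All tests of explanations in this part were chosen after the results were seen; the comparison of trained with naive libraries and its lists were set before the data were examined. Trained against naive is also the test of whether the difference from the shared controls is unequal in the groups labelled H2A.Z shRNA trained and naive. By that test Sgk1 differed by 0.85 on the log2 scale. The lists that differed had medians of 0.27 for immediate early genes, 0.089 for clock and glucocorticoid-induced genes, 0.079 for late activity genes and 0.019 for ion channel genes, and of -1.28 for interferon-stimulated genes, -0.13 for histone genes, -0.080 for ribosomal protein genes and 0.029 for heat shock genes. Among cell type markers the medians were 0.17 for CA1 neurons, -0.28 for dentate granule neurons, -0.12 for astrocytes, 0.17 for oligodendrocytes, -0.12 for endothelium, 0.22 for choroid plexus and ependyma, and -0.24 for meninges. None of these 15 lists passed with an estimated correlation (smallest adjusted p = 0.293 with an estimated correlation), and the calls of late activity, ion channel, ribosomal protein and heat shock genes and of the dentate, astrocyte, oligodendrocyte, endothelial, choroid plexus and meningeal markers ended without at least 1 single library. Single libraries were not tested for standing apart, because the gap test chosen for it needs groups of at least 4.

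Splits of the same libraries with a result at least as large were counted, with the real split included in each count. For the comparisons of 3 against 3 there are 10 splits, too few for a share under 0.05. In naive against control the real count past the adjusted threshold was 0 (limma; 1911 at an unadjusted p under 0.05; highest other 2), which all 10 splits reach whatever the data, so that count says nothing; 1 split gave at least the real 1911 genes at an unadjusted p under 0.05 (highest other 1470), and 3 gave at least 14 lists (highest other 20). In trained against control the counts were 6 for the real 1 gene (highest other 3), 3 for 951 genes at an unadjusted p under 0.05 (highest other 2983) and 7 for 10 lists (highest other 14). In trained against naive they were 7 for 1 gene (highest other 2), 1 for 1020 genes (highest other 1015) and 1 for 15 lists (highest other 14). For both H2A.Z shRNA groups against control, fitted as 2 groups, the real count was again 0 (limma; 1455 at an unadjusted p under 0.05), which 84 of 84 splits reach whatever the data. At least those 1455 genes were seen in 9 splits (highest other 2966) and at least 14 lists in 13 (highest other 16), so chance was not excluded for these 2 counts. The split that set control replicates 2 and 3 and trained replicate 2 apart called 493 genes, which points to a structure of the samples: these are the libraries with the lowest dentate marker means, 3.20, 3.07 and 3.43. The split that set control replicate 1 with trained replicates 1 and 3 gave the 2983 genes.

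Antigen presentation genes were higher in the libraries labelled H2A.Z shRNA, with a median log2 fold change of 1.42 by camera, a call not kept with an estimated correlation (adjusted p = 0.613 with an estimated correlation). A larger share of microglia as the whole cause would move these genes no more than the microglial markers, but the list exceeded the microglial list by 1.19 on the log2 scale (exact permutation p = 0.0238). This p is unadjusted, and the list was picked because it moved most. For the list mean itself the exact permutation p was also 0.0238, and 0.381 after adjustment over the lists. A single list cannot pass that adjustment with 84 assignments, so the adjusted value decides nothing. Naive replicate 2 alone is argued against too, since without it the median was 1.09, with 16 of 16 genes above 0. Both microglial markers and interferon-stimulated genes moved with part of the pattern, so a change of state in microglia, entry of immune cells, a response to the virus or to the hairpin, or a difference between the mice may account for it, and none of these was tested. H2afz did not differ, so no effect of lower H2A.Z can be read from it.

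Dentate granule markers were higher in the libraries labelled H2A.Z shRNA naive, with a median of 0.57 by camera, a call not kept with an estimated correlation (adjusted p = 0.587 with an estimated correlation). More dentate tissue in the dissected piece may account for this: the same markers also differed within the controls, where control replicate 1 exceeded the other two by a median of 0.72, with 19 of 19 higher, while 9 of 11 CA1 markers were lower there, with a median of -0.26. An effect of the hairpin on dentate neurons cannot be told apart from it, since the exact permutation p of the list mean for both H2A.Z shRNA groups against control was 0.0595, with a list difference of 0.45, and no measure of the dissected tissue is given in the labels.

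Immediate early genes and Sgk1 were higher in the trained than in the naive libraries, the former by camera and not with an estimated correlation (adjusted p = 0.293 with an estimated correlation). A different share of dentate tissue as the whole cause is argued against, because with the dentate marker mean as a covariate the immediate early median was 0.21, with 32 of 37 above 0, and Sgk1 stood at 0.88 (SE 0.07, limma adjusted p = 0.0228; range over alternatives 0.00161 to 0.0811). A general stress response of the tissue was taken to raise heat shock genes alike. Their median was 0.029, with an upper quartile of 0.07 below the immediate early median of 0.27. The list was still called higher by camera, with 19 of 24 above 0 (camera adjusted p = 0.0375, adjusted p = 0.738 with an estimated correlation). That call ended without naive replicate 1 or trained replicate 1. A rise of heat shock genes as large as that of the immediate early genes was therefore not seen. Stress that leaves the heat shock genes unchanged cannot be judged from them. Training, the foot shock, handling and stress of the mice stay open and untested, because no group among the samples separates them. No group labelled trained with a scrambled hairpin is among the samples either, so whether these differences depend on the H2A.Z hairpin was not tested. Clock and glucocorticoid-induced genes were higher by camera as well, with a median of 0.089 and 21 of 28 above 0. That call was not kept with an estimated correlation (adjusted p = 0.293 with an estimated correlation). Sgk1, Per1 and Tsc22d3 were among the members of that list with the smallest p, and Per1 is also in the immediate early list. Arc in control replicate 1, at 88.4, lay between the naive and the trained libraries, so whether that mouse was handled like the other controls may matter and was not tested.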

How the results depend on the processing

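Most alternatives here were chosen before the data were examined; those without small RNA genes, without genes listed at 0, without control replicate 1 and naive replicate 2 together, with the dentate markers as a covariate, and the permutation of list means were chosen after the results were seen, and genes named here outside the rule for named genes were chosen after their values were seen. Results for H2afz and H2afv kept their side of the threshold in every alternative, and the log2 fold change of H2afz without single libraries stayed between -0.06 and 0.01 in both groups against control. Of the values of named genes under alternatives, 11683 kept their side of the threshold, 41 passed it newly and 8 no longer did. Direction was compared only where a value was called in at least 1 of both fits, and 0 such values of named genes turned. Of the values of lists, 2570 kept their side of the threshold without such a turn, 116 passed newly and 204 no longer passed. A further 14, called in at least 1 of both fits, turned in the direction of camera, which weighs a list against all other genes. The median itself crossed 0 in 14 values of called lists, 8 of them with the dentate covariate. In all, 54 list calls were made, of which 26 held without each single library in turn. Of these, 20 also held under every other refit with the same list test. With an estimated correlation and with fry, 0 lists passed in all 4 comparisons, where camera passed 14, 10, 15 and 15. With an estimated correlation 1, 2, 3 and 1 lists had an unadjusted p under 0.05. Fry for changes in either direction passed 3, 2, 3 and 2. These were ion channel genes, p53 targets and astrocyte markers in naive against control, and immediate early and clock genes in trained against control. In trained against naive they were immediate early genes, clock genes and p53 targets, and in both against control p53 targets and astrocyte markers. The list calls thus depend on the correlation taken between the genes of a list, preset at 0.01 in camera. The exact permutation of list means passed 0 lists too, but in the comparisons of 3 against 3 its smallest possible p is 0.1, so it says nothing there; in both against control the smallest p was 0.0238, adjusted 0.381. With no filter, trained against control gave 0 higher genes (limma; Sgk1 adjusted p = 0.0502) and 16 lists; with a filter of 5 FPKM, naive against control gave 2 higher genes, Ralyl and A730017C20Rik. A fit of only the groups compared gave 3 higher genes in trained against control (Sgk1, B3gat2, H2-Aa) and 1 lower in trained against naive (Thoc6), and array weights gave 3 higher in naive against control (Ralyl, Capn3, A730017C20Rik) and 3 in both against control (Agmo, Cyld, Ralyl). Without control replicate 1 and naive replicate 2, naive against control gave 1 higher (Capn3) and 3 lower, trained against control 3 higher (Arc, Cyld, Sgk1) and 3 lower, and both against control 2 higher (Capn3, Cyld) and 3 lower, the lower ones being Far2, Mirlet7d and Snord8 each time; B3gat2, Thoc6 and Far2 are listed at 0 in 4, 5 and 7 libraries, and Ifi27l2a and Gm12238, the 2 genes called in both against control without naive replicate 1, in 7, so these calls rest on values that cannot be told from failed estimates; the microglial median in trained against naive turned to 0.11 and the endothelial one in both against control to -0.11. With the dentate covariate, trained against control gave 0 higher genes (limma) and trained against naive 1 lower (Cldn5), and lists turned in camera were, with their medians, late activity (0.16), respiratory chain (0.069), interneuron (0.13) and oligodendrocyte genes (0.031) in naive against control, interneuron genes (0.10) in trained against control, and interneuron (0.11) and oligodendrocyte genes (0.057) in both against control; medians that crossed 0 without such a turn were those of CA1 markers (0.028) in naive against control, CA1 markers (0.00073) and respiratory chain genes (0.011) in both against control, and late activity and choroid plexus genes (-0.025 each) in trained against naive. Without single libraries, higher and lower genes ranged from 0 to 13 and 0 to 5 in naive against control, 0 to 18 and 0 to 7 in trained against control, 0 to 2 and 0 to 24 in trained against naive, and 0 to 25 and 0 to 12 in both against control. The libraries that decided these counts were control replicate 1 (10 and 5, 18 and 7, 25 and 12 without it, such as Arc, Btg2, Cyld and Capn3 higher and Hcn2 and Slc7a10 lower), naive replicate 1 (13 higher in naive against control, 24 lower in trained against naive, 2 higher in both against control, with 5 of the 13 and 11 of the 24 in the fixed interferon list, such as Cxcl10 and Bst2), control replicate 3 (3, 2 and 3 higher in naive, trained and both against control, 1 lower in trained against naive), naive replicate 3 (4 higher and 1 lower, 2 higher, 4 higher, and 2 higher and 3 lower in trained against naive), control replicate 2, naive replicate 2 and trained replicate 3 (0 higher in trained against control), trained replicate 3 (0 higher in trained against naive), and trained replicates 1 and 2 (2 higher in trained against naive, Igj and Mir692-1 beside Sgk1; 1 in both against control without trained replicate 2). Without single libraries the median of the heat shock genes lay between -0.22 and 0.036 in both against control, turning without control replicate 1, and between -0.057 and 0.082 in trained against naive, turning without naive replicate 1 or trained replicate 1. The choroid plexus median in trained against control lay between -0.61 and -0.013, and the direction of camera turned without control replicate 3. In trained against naive the antigen presentation median lay between -0.63 and 0.40 and the microglial one between -0.23 and 0.11, and without naive replicate 2 both lists turned and passed as higher. With control replicate 1 and naive replicate 2 both left out, 17 list calls were kept with medians moved by over 1.5 times. The covariance of both differences from control was 0.106 with a pseudocount of 0.1, 0.0245 without small RNA genes and 0.0195 without genes listed at 0. What caused the other differences between alternatives was not tested. No paired analysis was possible because the labels give no pairs. Depth, with about 18.6 to 26.3 fragments per kilobase at 1 FPKM, limits genes near the filter most.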

Other observations

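The genes described here were chosen and grouped after their values were seen, and no test was run on these groupings. Some belong to lists described above, and those with a mean of at least 1 FPKM were tested singly by limma: with all 9 libraries no call was made among them, but some passed without a single library, such as Igj without trained replicate 1 and Cxcl10 without naive replicate 1. The immune genes did not move as 1 block. Class II genes such as Cd74 and H2-Aa had means of 3.35, 5.74 and 1.06 on the log2 scale in naive replicates 1, 2 and 3, and 3.42, 4.58 and 3.95 in trained replicates 1, 2 and 3, against 0.427 to 0.868 in the controls. Type I interferon-stimulated genes such as Isg15, Ifit1 and Cxcl10 had means of 2.18, 4.18 and 4.74 in the naive libraries, 1.23, 1.95 and 1.86 in the trained ones and 2.02, 3.03 and 2.18 in the controls. Naive replicate 3 thus had high type I genes with low class II genes, and all trained libraries the opposite. Interferon-inducible GTPase genes had means of 3.03, 5.42 and 3.26 on the log2 scale in the naive libraries. Their means were 1.45, 2.43 and 2.25 in the trained libraries and 1.21, 1.79 and 1.25 in the controls. Of these genes, Iigp1 stood at 10.3, 60.7 and 17.8 in the naive libraries, 1.55 to 3.69 in the trained ones and 1.01 to 2.33 in the controls. Ccl5, a chemokine of T cells, stood at 2.29, 9.21 and 2.63 in the naive libraries and at 3.82, 19.1 and 6.37 in the trained ones.

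Genes of antibody-producing cells were seen in 2 trained libraries. Igj, which encodes the joining chain of antibodies, stood at 61.6 in trained replicate 2 and 18.5 in trained replicate 3, and at no more than 0.184 in the other 7 libraries. Mzb1, a protein of the endoplasmic reticulum of B cells and plasma cells, stood at 7.87 and 1.94, and at no more than 0.0978 elsewhere. Cd79a, part of the B cell receptor, stood at 1.91 and 0.618, and Pou2af1, a coactivator of B cells, at 1.23 and 0.258. The fixed list of lymphocyte genes had 2 members tested, too few for a list test.

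All 9 libraries had the same pattern of sex-linked genes, with Ddx3y between 13.9 and 15.7 FPKM and Xist at no more than 0.0266. Of 82 tested genes other than small RNA genes that are listed at 0 in at least 1 library, 23 reach 10 FPKM or more in another. Snrpn, an abundant neuronal gene, is listed at 0 in control replicate 3 and lies between 199 and 251 in the other libraries, and Nptxr is at 16.7 in control replicate 3 and listed at 0 in the other 8. Such values cannot be told from failed estimates here.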
